A study of Mus musculus with 21 samples.

How the data were processed

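Splenic T cells of C57BL/6J mice were profiled by RNA sequencing at postnatal day 35. L-gp130fl/+;CD4Cre+/- mice, in which Cre expressed from the Cd4 promoter activates a constitutively active gp130 allele in T cells, were compared with CD4Cre+/- mice (controls). gp130, encoded by Il6st, is the signalling chain shared by the receptors of interleukin-6 and related cytokines. Per the labels' protocols, CD4+ cells were taken by positive selection on magnetic beads and CD8+ cells by negative selection, only RNA with an integrity number above 7 was used, and polyA libraries were sequenced unstranded as 150 bp paired ends. The labels give each library its own mouse number within its group, and its sex.

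Adapter trimming, quantification and testing tools are named without role or order: cutadapt 3.4, Trimmomatic 0.39, Salmon 1.5.2, edgeR 3.34.1 and build GRCm38, per the submitters' processing notes. The authors deposited estimated counts per gene in a table for each cell type. Per the values in the files, these estimated counts are TPM values scaled by gene length and library total: 99.6% of CD4 entries compared lay within 1% of that product. Of the CD8 entries 36.9% did, and 99.7% did after 1 constant per gene. Per the file headers, the authors deposited for each library Salmon's estimated counts per transcript (reads) and TPM. TPM was used only for that comparison. The deposited tables of normalised CPM list 15031 genes (CD4) and 14254 genes (CD8). They equal the deposited gene counts as CPM times 1 factor per library, per the values in the files. The filter behind the listed genes and the annotation release are not given in the sources used here.

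Gene names and GRCm38 positions came from GENCODE mouse release 21, in which 51115 of the 51201 gene IDs had a symbol. Of the transcripts, 694 had no match, with 0.144% to 0.209% of each library's reads. Libraries of a group were compared in pairs before averaging. The lowest chi-square per gene was 9.75, so no library looked like a second copy of another.

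Estimated gene counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalisation, robust quasi-likelihood F test, 2-sided, Benjamini-Hochberg adjustment, called at an adjusted p under 0.05), with the labelled sex as covariate. CD4 and CD8 libraries were fitted separately. Fold changes are L-gp130 over control. Their standard error (SE), on the log2 scale, was taken as the size of the log2 fold change over the square root of its F statistic. Levels are TMM-normalised CPM, with SD. The difference between the effects in CD4 and CD8 cells was tested as the cell type by genotype term over all 21 libraries. That test had been designed for joined gene tables on the condition that no table was scaled by itself. The gene tables are length-scaled per table, so it was run on Salmon's reads per transcript summed per gene, and the joined tables became an added alternative.

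Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, 2-sided and adjusted over the 26 lists. Beside it stood camera with an estimated correlation, fry, and counts of members called over all genes and with p adjusted over the list alone. At the preset correlation camera also called many lists in regrouped libraries where edgeR called 0 genes. Its adjusted p at that setting is therefore weak evidence by itself. The 13 function lists were gp130-STAT3 signalling, TH17, TH1, TH2, TFH (follicular helper), Treg, naive T cell, effector-memory T cell, interferon response, cell cycle, cytotoxic, inhibitory receptor and glycolysis. The 13 context lists were gamma-delta T cell, other T lineage, B cell, plasma cell, monocyte-macrophage, dendritic cell, neutrophil, erythroid, NK cell, platelet, stroma, immediate early genes and mitochondrial transcripts. Some genes sit in more than 1 list, such as Pdcd1, Il21, Tigit and Ctla4.

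Genes were named by a rule. It takes Il6st, Stat3 and Socs3 in every library. From each function list it takes up to 3 called members with the smallest adjusted p. It then takes the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap of the groups, leaving out gene models, immunoglobulin and T cell receptor segments and sex genes. For the interaction it takes the 8 smallest adjusted p, and for context lists up to 3 members. Some genes that the rule takes are not reported here. Members named because few in a list moved in their direction were chosen after their values were seen. Groups, tests, lists, the naming rule and the listed alternatives were chosen before the data were examined. Alternatives chosen after seeing the data are named as such.

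Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a filter at CPM 1, no sex covariate, females or males alone, reads per transcript summed per gene, the authors' listed genes, stricter thresholds, a replicate block and leaving out each library. Chosen after seeing the data were the sex read from Xist and Ddx3y, thinning of the CD4 libraries to equal depth, GC and length offsets, CD4 fits without 2 doubted libraries, CD8 fits with part of the controls, and the joined gene tables.

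Simulated counts with 200 seeded genes per comparison tested the fits. At 1.5-fold, 2-fold and 4-fold the CD4 fit (14852 genes in that step) recovered 32.8%, 58.2% and 90.9% of seeded genes with 6 false calls. The CD8 fit (13995 genes) recovered 28.4%, 74.6% and 87.9% with 4 false calls. The interaction fit (15527 genes) recovered 32.8%, 56.7% and 71.2% with 5. Ratios of low counts carry exact 95% intervals, and a group at 0 was set to a floor of 3 counts over the group. Both cover counting error only. Genes that overlap another gene on either strand, pseudogenes and near-identical copies are uncertain, because the libraries carry no strand. Of the 153 genes that the rule takes, 26 overlap another tested gene, among them Stat3, Itgae, Ccr9, Irf9, Pfkp, Gapdh, Cxcr6, Tpi1, Cd160, mt-Nd5 and mt-Nd6. So do Il6ra, Cxcr5, Foxp3, Tmem176a, Tmem176b, Pou6f1 and Ppm1j, named outside the rule.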

Results

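Polyadenylated RNA was measured in 21 libraries of spleen cells selected for CD4+ or CD8+ T cells. There were 6 from CD4+ cells of L-gp130 mice and 6 from CD4+ cells of controls. Another 3 were from CD8+ cells of L-gp130 mice and 6 from CD8+ cells of controls. Gene count totals per library were 17781085 to 21226510 in L-gp130 CD4, 27855757 to 35869208 in control CD4, 17217364 to 19476881 in L-gp130 CD8 and 17719183 to 19286396 in control CD8 libraries. In CD4 cells depth therefore went with genotype, with no overlap. By label, 4 of 6 L-gp130 CD4, 1 of 6 control CD4, 2 of 3 L-gp130 CD8 and 4 of 6 control CD8 libraries came from males. Reads of Xist and the Y-linked gene Ddx3y matched the labelled sex in all but 1 of the 21 libraries. The exception, control CD4 replicate 5, was labelled female and had Xist at 0.12 CPM and Ddx3y at 124 CPM. L-gp130 CD4 replicate 1 stood apart from the other CD4 libraries on the second principal component (56.9, others -36.8 to 22.4), which held 13.98% of the variance. In CD8 cells that component (12.9%) separated control replicates 1 to 3 (-27.9 to -23.4) from control replicates 4 to 6 (6.86 to 31.3).

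The design asks what constitutively active gp130 does to the transcripts of T cells. Il6st (ENSMUSG00000021756, chromosome 13, 112464070 to 112510086, GRCm38), the gene of gp130 itself, averaged 271 ± 72.2 CPM (SD, n = 6) in L-gp130 CD4 libraries and 368 ± 19.5 (n = 6) in controls. The L-gp130 values were 132, 339, 270, 298, 281 and 306 CPM in replicates 1 to 6, and the controls ranged from 348 to 395. The log2 fold change of -0.32 ± 0.18 (SE) did not pass edgeR's test (adjusted p = 0.245). Without L-gp130 replicate 1 it did (adjusted p = 0.0122). In CD8 cells Il6st fell from 261 ± 20.3 (n = 6) to 183 ± 11.98 CPM (n = 3), a log2 fold change of -0.52 ± 0.08 (edgeR adjusted p = 0.00198). The 3 L-gp130 values were 185, 193 and 170 CPM, and the 6 controls lay between 239 and 291. The gp130 sequence held by the allele is not given in the sources used here, so Il6st counts need not include its transcript.

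Stat3 and Socs3 were higher in every L-gp130 library than in every control library of the same cell type. Stat3 (ENSMUSG00000004040, chromosome 11, 100885098 to 100939540), the transcription factor activated by gp130, rose from 262 ± 19.4 to 394 ± 17.1 CPM in CD4 cells, with values of 376, 421, 392.4, 377, 404 and 394 against 247, 289, 259, 237, 261 and 278. In CD8 cells it rose from 210 ± 22.6 to 347 ± 15.7 CPM, with values of 329, 357 and 356 against 191, 200, 220, 219, 186 and 247. The log2 fold changes were 0.63 ± 0.07 (edgeR adjusted p = 4.47e-05) and 0.73 ± 0.07 (adjusted p = 0.000199). Stat3 overlaps the end of Stat5a on the other strand, and Stat5a had fewer reads. Socs3 (ENSMUSG00000053113, chromosome 11, 117966079 to 117970047), a feedback inhibitor of gp130 signalling, rose from 127 ± 9.29 to 358 ± 60.0 CPM in CD4 cells, with values of 264, 432, 353, 391, 388 and 319 against 119, 116, 135, 126, 140 and 125. In CD8 cells it rose from 141 ± 23.0 to 483 ± 35.8 CPM, with values of 444, 514 and 492 against 143, 164, 133, 115, 171 and 119. The log2 fold changes were 1.55 ± 0.12 (edgeR adjusted p = 4.02e-06) and 1.79 ± 0.12 (adjusted p = 1.23e-05).

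**Figure D1:**
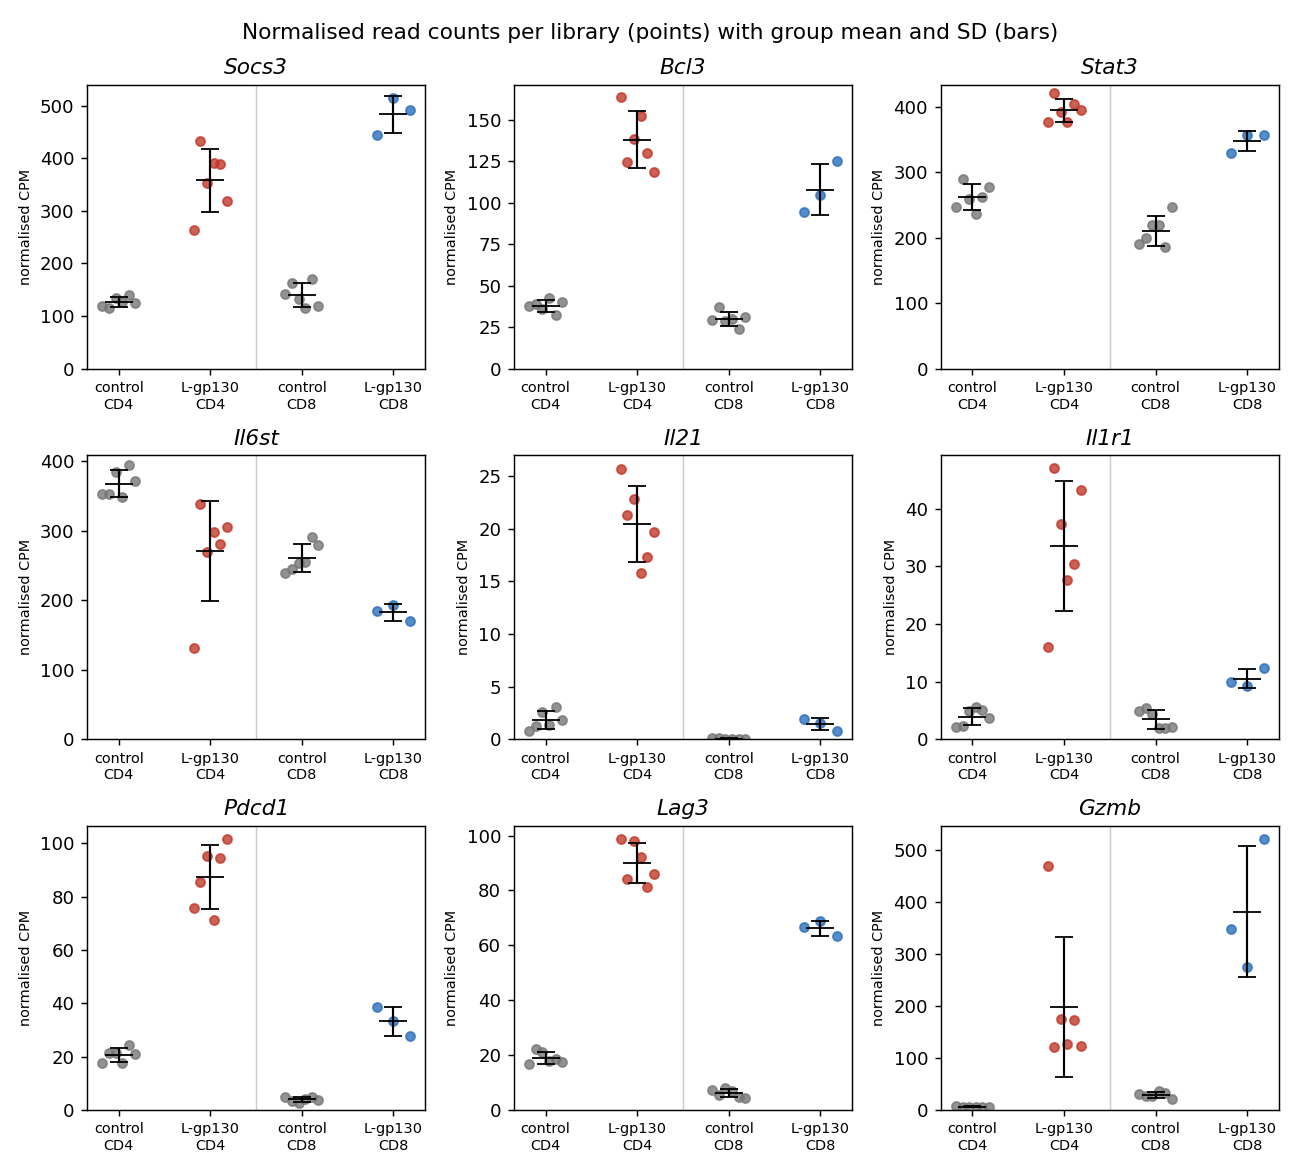
Normalised CPM (vertical axes from 0) of 9 genes, with 1 point per library, and the mean and SD of each group as bars. Socs3, Bcl3, Stat3, Pdcd1 and Lag3 separate the genotypes in both cell types, and L-gp130 CD4 replicate 1 lies apart for Il6st (132 CPM) and Gzmb (470 CPM).

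In CD4 cells of L-gp130 mice, 9 of 11 tested TFH, 8 of 11 TH17, 7 of 16 gp130-STAT3 and 7 of 13 inhibitory receptor genes rose, while 2 TH17 and 2 gp130-STAT3 genes fell. Of 14 naive T cell genes 9 fell, in a list whose call was lost with an estimated correlation (camera adjusted p = 0.193). Batf, an AP-1 family factor used by TH17 and TFH cells, rose from 24.4 ± 1.42 to 73.4 ± 5.78 CPM (n = 6 each), a log2 fold change of 1.62 ± 0.08. Bcl3, an atypical inhibitor of the NF-kB family and STAT3 target, rose from 37.9 ± 3.56 to 138 ± 17.3 CPM (log2 1.77 ± 0.10). Il21, the cytokine of TFH and TH17 cells, rose from 1.81 ± 0.85 to 20.4 ± 3.61 CPM (log2 3.74 ± 0.32). Pdcd1, which encodes the inhibitory receptor PD-1, rose from 20.5 ± 2.58 to 87.3 ± 12.02 CPM (log2 2.19 ± 0.11).

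Of 16 tested gp130-STAT3 genes, 7 rose and 2 fell in CD4 cells (9 and 2 adjusted over the list alone), and camera called the list up (adjusted p = 5.86e-11). The members that fell were Il6ra, the interleukin-6 receptor chain (log2 -1.23), and Il4ra, the interleukin-4 receptor chain (log2 -0.43). Of 11 tested TH17 genes, 8 rose and 2 fell (also 8 and 2 adjusted over the list alone; camera adjusted p = 4.64e-09). Il1r1, the interleukin-1 receptor, rose by 3.49 ± 0.27 on the log2 scale and Maf, a transcription factor of interleukin-producing T cells, by 0.82 ± 0.09. The members that fell were Tmem176a (log2 -0.49) and Tmem176b (log2 -0.45). Of 11 tested TFH genes 9 rose and 0 fell (9 adjusted over the list alone; camera adjusted p = 1.99e-21), among them the costimulatory receptor Icos (log2 1.45 ± 0.10). Of 13 inhibitory receptor genes 7 rose and 0 fell (7 adjusted over the list alone; camera adjusted p = 6.75e-18). Lag3 rose by 2.25 ± 0.10 and Tigit by 2.45 ± 0.14 on the log2 scale. Of 14 Treg genes 7 rose and 0 fell (10 adjusted over the list alone; camera adjusted p = 3.36e-11), with Itgae, the integrin chain CD103, at a log2 fold change of 2.51 ± 0.19 and Ctla4 at 0.86 ± 0.09. Foxp3, the factor that defines regulatory T cells, had a log2 fold change of 0.31 ± 0.19 (edgeR adjusted p = 0.268). These 5 calls held with an estimated correlation, with camera adjusted p from 0.000285 to 0.0259, as did that of the immediate early genes (adjusted p = 0.0259, of which 5 of 12 rose and 0 fell). No other CD4 list held. Without L-gp130 replicate 1 and control replicate 5, 8 of 16 gp130-STAT3, 9 of 12 TH17, 9 of 11 TFH, 9 of 13 inhibitory receptor and 8 of 14 Treg genes rose.

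All 22 cell cycle genes rose in CD4 cells (22 adjusted over the list alone; camera adjusted p = 4e-16, and adjusted p = 0.187 with an estimated correlation), including the replicative helicase subunits Mcm4 (log2 0.73 ± 0.10) and Mcm6 (0.90 ± 0.13) and the spindle checkpoint kinase Bub1 (1.80 ± 0.29). All 22 also rose without the 2 doubted libraries, and 21 with the sex read from Xist and Ddx3y. Of 14 glycolysis genes 9 rose and 0 fell (12 adjusted over the list alone; camera adjusted p = 1.24e-08, and adjusted p = 0.187 with an estimated correlation), with log2 fold changes of 0.94 ± 0.11 for Gapdh, 0.85 ± 0.11 for Pgam1 and 0.75 ± 0.09 for Pfkp. Of 14 naive T cell genes 0 rose and 9 fell (12 adjusted over the list alone; camera adjusted p = 7.61e-08, and adjusted p = 0.193 with an estimated correlation). Klf2, a regulator of T cell trafficking, had a log2 fold change of -0.76 ± 0.09, and Ccr9, a gut homing receptor, of -1.19 ± 0.17. Beside the cell cycle genes, the erythroid list had a median log2 fold change of 1.93 in the same libraries, with 0 of 11 members called. Whether the cell cycle transcripts rose in T cells or in other cells was not tested.

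The effector lists moved less uniformly in CD4 cells. Of 16 effector-memory genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0015, and adjusted p = 0.448 with an estimated correlation). The calcium-binding S100a6 rose by 1.69 ± 0.17, S100a11 by 0.80 ± 0.10 and S100a4 by 0.86 ± 0.19 on the log2 scale, and Fasl, the death ligand, fell (log2 -0.79). The S100a4 call ended without control replicate 1 (edgeR adjusted p = 0.0765). Of 14 TH1 genes 4 rose and 0 fell (6 adjusted over the list alone; camera adjusted p = 0.00233, and adjusted p = 0.457 with an estimated correlation). They included the chemokine receptor Cxcr3 (log2 0.86 ± 0.15) and the chemokines Ccl3 (2.37 ± 0.52) and Ccl4 (2.58 ± 0.70). Without L-gp130 replicate 6 the calls of Ccl3 (edgeR adjusted p = 0.0774) and Ccl4 ended, and that of Ccl4 also without control replicate 1 (adjusted p 0.103 to 0.179). Over single libraries left out, the Ccl4 value went from 1.81 without control replicate 1 to 3.31 without L-gp130 replicate 2. Of 6 tested TH2 genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0145, and adjusted p = 0.169 with an estimated correlation). The receptors Il9r (log2 1.08 ± 0.13) and Ccr4 (0.70 ± 0.12) rose, and Gata3, the lineage factor of TH2 cells, fell (-0.44 ± 0.08).

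Of 16 cytotoxic genes 4 rose and 2 fell in CD4 cells (6 and 3 adjusted over the list alone), and camera did not call the list (adjusted p = 0.141, or 0.00359 without L-gp130 replicate 1 and 0.00695 without the 2 doubted libraries). Gzmb, the protease granzyme B, rose from 5.80 ± 0.73 to 198 ± 135 CPM (log2 4.67 ± 0.36), with L-gp130 replicate 1 at 470 CPM and the mean of the others at 144. Cd8a, a marker of CD8 T cells, was at 36 ± 28.9 CPM in L-gp130 and 10.98 ± 2.46 CPM in control CD4 libraries (edgeR adjusted p = 0.0700, or 0.00598 without L-gp130 replicate 1). It was also called without the 2 doubted libraries (0.00840), without the sex covariate (0.00834) and with the sex read from Xist and Ddx3y (0.0366). DESeq2 (adjusted p = 0.0247) and edgeR in females alone (0.0451) called it too, and the other settings did not. Klrd1, the killer lectin receptor CD94, fell (log2 -0.59 ± 0.14), a call that ended without L-gp130 replicate 6 (edgeR adjusted p = 0.0570). Nkg7, a granule protein, rose (log2 1.38 ± 0.40). Its call ended in 7 of 12 fits that left out 1 library, those without L-gp130 replicate 6 or any 1 of the 6 controls (adjusted p 0.0513 to 0.161). Of 18 interferon response genes 0 rose and 2 fell (2 adjusted over the list alone), and camera did not call the list (adjusted p = 0.219, or 0.00471 without control replicate 1). Irf9, a subunit of the interferon-stimulated factor, had a log2 fold change of -0.39 ± 0.10, and its call ended without L-gp130 replicates 2 or 6 (edgeR adjusted p 0.101 to 0.114). Usp18, a brake on interferon signalling, was at -0.83 ± 0.25, and its call ended in 7 fits, those without L-gp130 replicates 2, 3 or 6 or control replicates 3, 4, 5 or 6 (adjusted p 0.0505 to 0.138).

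The largest rises in CD4 cells were in genes almost unread in controls. Moxd1, a monooxygenase gene (chromosome 10, from 24223517), had 1143 counts in L-gp130 and 3 in control libraries, a depth-adjusted ratio of 640 (95% counting interval 218 to 3107). Vwde had 664 and 3 counts, a ratio of 372 (127 to 1807), and its fitted log2 fold change of 8.42 was 9.26 without control replicate 3. On the log2 scale Vat1l rose by 6.80 ± 0.78, Fbn2, a fibrillin, by 6.12 ± 0.52, Sostdc1, a secreted BMP antagonist, by 6.03 ± 0.42, Lrrc6 by 6.00 ± 0.35, and Apol11a by 5.76 ± 1.36. Sostdc1 was lowest in L-gp130 replicate 1, at 5.84 CPM against a mean of 22.7 in the others. The Apol11a call ended without L-gp130 replicate 6 or control replicate 1 (edgeR adjusted p 0.0591 to 0.165). Its value was 4.69 without L-gp130 replicate 6, and 6.53 and 6.46 without L-gp130 replicate 2 and control replicate 4. Kirrel3os (5.48 ± 0.79) lies antisense to Kirrel3 (5.21). Unstranded reads of any exon sequence that they share cannot be told apart, and whether their exons overlap was not checked. The largest falls were in the motor protein gene Myo6 (log2 -2.61 ± 0.28), Epb41l1 (-2.52 ± 0.26), the fatty acid elongase Elovl7 (-2.51 ± 0.34, or -3.25 without L-gp130 replicate 6), Sp6 (-2.31 ± 0.30), Pdlim4 (-2.25 ± 0.12), the collagens Col3a1 (-2.48 ± 0.42) and Col14a1 (-2.28 ± 0.29), and Siglech, a marker of plasmacytoid dendritic cells (-2.17 ± 0.38).

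Transcripts of other cell types also differed between the genotypes in the CD4 libraries. In control CD4 libraries, normalised over all libraries, the haemoglobin gene Hbb-bs averaged 4712 CPM and the B cell gene Cd79a 117, beside 727 for Cd4. Of 11 plasma cell genes 8 rose and 0 fell (8 adjusted over the list alone; camera adjusted p = 7.61e-08, and adjusted p = 0.125 with an estimated correlation), with Jchain at 116 against 35.3 CPM. Ighg2b and Ighg2c rose too, but reads may be shared among related immunoglobulin genes, which was not measured. Of 12 B cell genes 0 rose and 5 fell (10 adjusted over the list alone; camera adjusted p = 0.000227, and adjusted p = 0.435 with an estimated correlation), with Fcrla at 13.6 against 27.7 CPM (call lost without control replicate 1, edgeR adjusted p = 0.0905). Of 14 monocyte-macrophage genes 1 fell (0 adjusted over the list alone; camera adjusted p = 0.0187, and adjusted p = 0.580 with an estimated correlation), but 10 fell without the 2 doubted libraries and 0 with the sex read from Xist and Ddx3y. The dendritic cell list (3 of 11 fell, 4 adjusted over the list alone) had camera adjusted p = 0.0082, and adjusted p = 0.265 with an estimated correlation. The NK cell list (1 of 8 fell, 3 adjusted over the list alone) had 0.0341 and, with an estimated correlation, adjusted p = 0.448. The stroma list (2 of 7 fell, 5 adjusted over the list alone) had 0.00081 and, with an estimated correlation, adjusted p = 0.193. The erythroid list (0 of 11 called, with or without the list alone) was higher, with camera adjusted p = 0.0224, and adjusted p = 0.580 with an estimated correlation. Without L-gp130 replicate 2 camera no longer called the dendritic cell (adjusted p = 0.0972) and monocyte-macrophage (0.0970) lists, without L-gp130 replicates 2 or 4 the NK cell list (0.0652 to 0.143), and without L-gp130 replicate 6 the erythroid list (0.319). With the sex read from Xist and Ddx3y, and without the sex covariate, camera no longer called the NK cell (0.118 and 0.2502), erythroid (0.118 and 0.236) and monocyte-macrophage lists (0.173 and 0.311), nor the NK cell list in libraries thinned to equal depth (0.0535) or filtered at CPM 1 (0.118).

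Immediate early genes, which respond to stimulation and handling, rose in 5 of 12 cases (6 up and 1 down adjusted over the list alone; camera adjusted p = 0.00149), among them Egr2 (log2 1.43) and Fos (1.23). Camera did not call the gamma-delta T cell (adjusted p = 0.134; 1 up), neutrophil (0.174; 0 called), platelet (0.0739; 1 up), mitochondrial (0.472; 0 called) or other T lineage lists (0.605; 1 down), and these counts were equal when adjusted over the list alone except for the last (1 up and 1 down). It did call the platelet list without L-gp130 replicates 2 or 5 or control replicates 1 or 4, without the sex covariate and with the sex from reads (adjusted p 0.0180 to 0.0462), the gamma-delta list without L-gp130 replicate 2, control replicate 6 or the sex covariate (0.0270 to 0.0492), and the neutrophil list without control replicate 1 (0.0183). In the other T lineage list the median (-0.03) and the mean (0.18) differed in sign. Cd4 itself was at 731 and 755 CPM (edgeR adjusted p = 0.858).

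As genes changed by L-gp130 in CD4 T cells, edgeR called 2836 of 15016 tested, 1673 up and 1163 down, and 942 changed at least 2-fold (664 up, 278 down). The groups' values did not overlap in 1698 of the called genes and in 2032 of all tested genes, where chance gives 0.216% of them. The count was 3340 without the 2 doubted libraries, 1411 without L-gp130 replicate 6, 1529 without control replicate 1, and 19 among males alone, with 1 control male by label. It was 3295 with the sex read from Xist and Ddx3y.

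In CD8 cells of L-gp130 mice, Socs3, Stat3 and Bcl3 of the gp130-STAT3 genes, 7 of 11 tested TFH and 6 of 13 inhibitory receptor genes rose, and 2 inhibitory receptor, 10 of 14 naive T cell and 7 of 18 interferon response genes fell. With an estimated correlation camera's adjusted p = 0.0169 for the TFH, 0.0770 for the inhibitory receptor, 0.112 for the naive T cell and 0.247 for the interferon list. Bcl3 rose from 30.1 ± 4.38 (n = 6) to 108 ± 15.6 CPM (n = 3), a log2 fold change of 1.84 ± 0.12. Lag3 rose from 6.08 ± 1.40 to 66.2 ± 2.78 CPM (log2 3.44 ± 0.16) and Pdcd1 from 3.90 ± 0.88 to 33.3 ± 5.47 CPM (log2 3.09 ± 0.15). Gzmb rose from 28.7 ± 5.23 to 381 ± 126 CPM (log2 3.72 ± 0.21).

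Of 11 tested TFH genes 7 rose and 0 fell in CD8 cells (7 up and 1 down adjusted over the list alone; camera adjusted p = 4.78e-09), with Icos at a log2 fold change of 0.92 ± 0.08 and Tox2, a nuclear factor of TFH and exhausted cells, at 3.28 ± 0.37. This was the only CD8 list call that held with an estimated correlation (adjusted p = 0.0169). Of 13 inhibitory receptor genes 6 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 4.78e-09, and adjusted p = 0.0770 with an estimated correlation), with Cd160 at 1.46 ± 0.12. The members that fell were Tox, a regulator of exhausted T cells (log2 -0.50), and Entpd1, the ectonucleotidase CD39 (log2 -1.09). Of 14 gp130-STAT3 genes 6 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.000179, and adjusted p = 0.159 with an estimated correlation). Those that fell were Il6st and Il6ra (log2 -0.77). Of 12 TH17 genes 4 rose and 0 fell (5 adjusted over the list alone; camera adjusted p = 0.00384, and adjusted p = 0.290 with an estimated correlation), and against control replicates 1 to 3 alone camera no longer called the list (adjusted p = 0.0802). Il21 had 83 against 5 counts (ratio 33.0, counting interval 13.6 to 104), the receptor gene Ahr rose by 1.02 ± 0.15 on the log2 scale, and Il1r1 by 1.59 ± 0.35. The Il1r1 call ended without L-gp130 replicate 3 (edgeR adjusted p = 0.0766).

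Of 13 Treg genes 6 rose and 2 fell in CD8 cells (8 and 2 adjusted over the list alone; camera adjusted p = 0.000455, and adjusted p = 0.185 with an estimated correlation). Gpr83, an orphan receptor of regulatory T cells, rose by 1.83 ± 0.13 on the log2 scale. Foxp3 rose by 1.63 ± 0.25. Itgae (log2 -1.06 ± 0.13), which CD8 cells also express, and Tnfrsf18, the costimulatory receptor GITR (-0.64 ± 0.09), fell. Cd4 transcripts were at 11.6 CPM in L-gp130 CD8 libraries, 12.5 in control replicates 1 to 3 and 4.12 in control replicates 4 to 6. Of 14 TH1 genes 5 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.0116, and adjusted p = 0.2495 with an estimated correlation), and camera no longer called the list without L-gp130 replicate 3 (adjusted p = 0.132) or against control replicates 1 to 3 alone (0.0554). Il12rb1, an interleukin-12 receptor chain, rose by 0.77 ± 0.10 and the chemokine Ccl5 by 1.03 ± 0.16, and the chemokine receptor Cxcr6 fell (log2 -0.78 ± 0.16). Of 6 TH2 genes 4 rose and 0 fell (4 up and 1 down adjusted over the list alone; camera adjusted p = 0.0116, and adjusted p = 0.159 with an estimated correlation). They included the interleukin-33 receptor Il1rl1 (log2 2.10 ± 0.30), Ccr4 (1.61 ± 0.26) and Il4 (1.83 ± 0.38), whose call ended without L-gp130 replicate 3 (edgeR adjusted p = 0.0573).

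Of 14 naive T cell genes 0 rose and 10 fell in CD8 cells (11 adjusted over the list alone; camera adjusted p = 3.74e-10, and adjusted p = 0.112 with an estimated correlation). Dapl1, a gene of naive CD8 T cells, had a log2 fold change of -2.34 ± 0.15, Ccr9 of -1.66 ± 0.16 and S1pr1, the receptor for egress from lymphoid organs, of -0.59 ± 0.08. Of 16 effector-memory genes 9 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 3.39e-06, and adjusted p = 0.185 with an estimated correlation). S100a6 rose by 1.67 ± 0.12, S100a4 by 1.27 ± 0.15 and Anxa2 by 0.78 ± 0.12, and Ahnak fell (log2 -1.05). Of 18 interferon response genes 0 rose and 7 fell (1 up and 12 down adjusted over the list alone; camera adjusted p = 4.98e-06, and adjusted p = 0.247 with an estimated correlation). Ifit3 and Ifit1, antiviral effectors, had log2 fold changes of -1.50 ± 0.15 and -1.66 ± 0.23, and Usp18 of -1.39 ± 0.15. Against control replicates 1 to 3 alone 5 of the 18 fell, and against control replicates 4 to 6 alone 12 fell and 1 rose.

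Of 22 cell cycle genes 21 rose and 0 fell in CD8 cells (22 adjusted over the list alone; camera adjusted p = 1.52e-20, and adjusted p = 0.159 with an estimated correlation). The mitotic kinase Plk1 rose by 1.498 ± 0.16, the helicase subunit Mcm2 by 0.57 ± 0.07 and Rrm2, a ribonucleotide reductase subunit, by 1.44 ± 0.17 on the log2 scale. Of 14 glycolysis genes 10 rose and 0 fell (11 adjusted over the list alone; camera adjusted p = 8.85e-08, and adjusted p = 0.185 with an estimated correlation), with Tpi1 at 0.91 ± 0.09, Gapdh at 0.57 ± 0.06 and Pgam1 at 0.65 ± 0.09. Of 16 cytotoxic genes 5 rose and 0 fell (5 adjusted over the list alone; camera adjusted p = 0.000455, and adjusted p = 0.185 with an estimated correlation), with the lectin receptor Klrc1 at 1.09 ± 0.10 and Gzma, granzyme A, at 0.90 ± 0.16. Beside them, 4 of 11 erythroid genes rose, including the red cell factor Klf1 (log2 1.63). Which cells the cell cycle transcripts came from was not tested. Cell cycle counts against control replicates 1 to 3 alone and 4 to 6 alone were 22 and 20 of 22.

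The largest rises in CD8 cells were in Crhbp, a binding protein of corticotropin-releasing hormone (log2 6.65 ± 0.45), Moxd1 (6.01 ± 0.95, with 321 against 10 counts), Podxl, a podocalyxin (5.31 ± 0.53, or 4.26 without L-gp130 replicate 1), the secreted protease gene Htra3 (5.25 ± 0.41), Lrrc6 (4.85 ± 0.26), Gzmb, Galr3 (3.58 ± 0.36) and Lag3. Without L-gp130 replicate 3 the Moxd1 value was 10.06 and that of Crhbp 7.36, and without control replicates 3 and 6 they were 8.33 and 7.34 in turn. Galr3 overlaps Gcat, which rose too (log2 2.07). The largest falls were in the collagen Col14a1 (log2 -4.28 ± 0.65), the chemokine receptor Ccr3 (-3.12 ± 0.44), the scavenger receptors Stab2 (-2.94 ± 0.45) and Mrc1 (-2.84 ± 0.35), the potassium channel Kcnj16 (-2.78 ± 0.42, or -3.39 without L-gp130 replicate 3), the complement gene C1qa (-2.76 ± 0.36) and the integrin Itga9 (-2.70 ± 0.55). The Itga9 call ended without L-gp130 replicate 3 (edgeR adjusted p = 0.0533). C1qa belongs to the monocyte-macrophage list, in which 8 of 14 genes fell. Whether these largest falls lie in the CD8 T cells or in other cells was not tested. Rpl36a-ps2 (-2.89 ± 0.78), a pseudogene with near-identical copies, is uncertain, and its call ended in 8 of 9 fits that left out 1 library, all but that without L-gp130 replicate 1 (adjusted p 0.0563 to 0.0838). Its value was -2.27 without L-gp130 replicate 1 and -3.49 without L-gp130 replicate 2.

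Beside these, 8 of 14 monocyte-macrophage genes fell in the CD8 libraries (10 adjusted over the list alone; camera adjusted p = 1.48e-07, and adjusted p = 0.232 with an estimated correlation), with C1qb at 4.21 against 24.0 CPM. Of 8 NK cell genes 4 fell (5 adjusted over the list alone; camera adjusted p = 0.00374, and adjusted p = 0.309 with an estimated correlation), with Ncr1 at 9.12 against 20.3 CPM, and against control replicates 4 to 6 alone camera no longer called the list (adjusted p = 0.120). Of 12 plasma cell genes 2 rose (2 adjusted over the list alone; camera adjusted p = 0.000455, and adjusted p = 0.335 with an estimated correlation). They were Ighg1 and Ighg3, which are uncertain because reads may be shared among related immunoglobulin genes. Both calls ended without L-gp130 replicate 1, and that of Ighg1 also without L-gp130 replicate 3 (edgeR adjusted p 0.0604 to 0.0775). Of 9 gamma-delta T cell genes 5 rose (6 adjusted over the list alone; camera adjusted p = 0.000581, and adjusted p = 0.2495 with an estimated correlation), with Cd163l1 at 58.4 against 25.1 CPM. Of 12 mitochondrial transcripts 7 rose (8 adjusted over the list alone; camera adjusted p = 0.000317, and adjusted p = 0.335 with an estimated correlation). The erythroid (4 up, also adjusted over the list alone) and immediate early lists (1 up and 1 down; 1 up adjusted over the list alone) both had camera adjusted p = 0.0438, and adjusted p = 0.546 with an estimated correlation. The erythroid call ended without L-gp130 replicate 1 or control replicates 1, 2, 5 or 6 (adjusted p 0.0542 to 0.154), and the immediate early call without any 1 of the L-gp130 libraries or control replicates 4, 5 or 6 (0.0506 to 0.0962). Both also ended with GC and length offsets (0.0629 and 0.0526) and against control replicates 1 to 3 alone (0.211 and 0.448), and the erythroid call against control replicates 4 to 6 alone (0.0926). Camera did not call the B cell (adjusted p = 0.408; 0 called), dendritic cell (0.610; 1 up, median and mean of different sign), neutrophil (0.408; 0 called), platelet (0.855; 0 called), stroma (0.308; 0 called, 2 up adjusted over the list alone) or other T lineage lists (0.187; 2 down). In the last, Cd8b1 fell from 1009 to 633 CPM and Cd8a from 1083 to 844, the latter call ending without L-gp130 replicate 1 (edgeR adjusted p = 0.0711). The B cell median was -0.999 against control replicates 1 to 3 alone and 0.59 against control replicates 4 to 6 alone. Against control replicates 1 to 3 alone camera called the B cell (adjusted p = 0.000151) and neutrophil lists (0.000215) lower, and the neutrophil list also without control replicate 6 (0.0317).

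As genes changed by L-gp130 in CD8 T cells, edgeR called 2996 of 14254 tested, 1495 up and 1501 down, and 836 changed at least 2-fold (597 up, 239 down). The groups did not overlap in 2617 called genes and in 3438 of all tested genes, where chance gives 2.38%. With 3 L-gp130 libraries, single libraries weighed heavily: the count was 1374 without replicate 1, 1865 without replicate 2 and 1554 without replicate 3, and 133 among females alone, with 1 L-gp130 female.

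**Figure D2:**
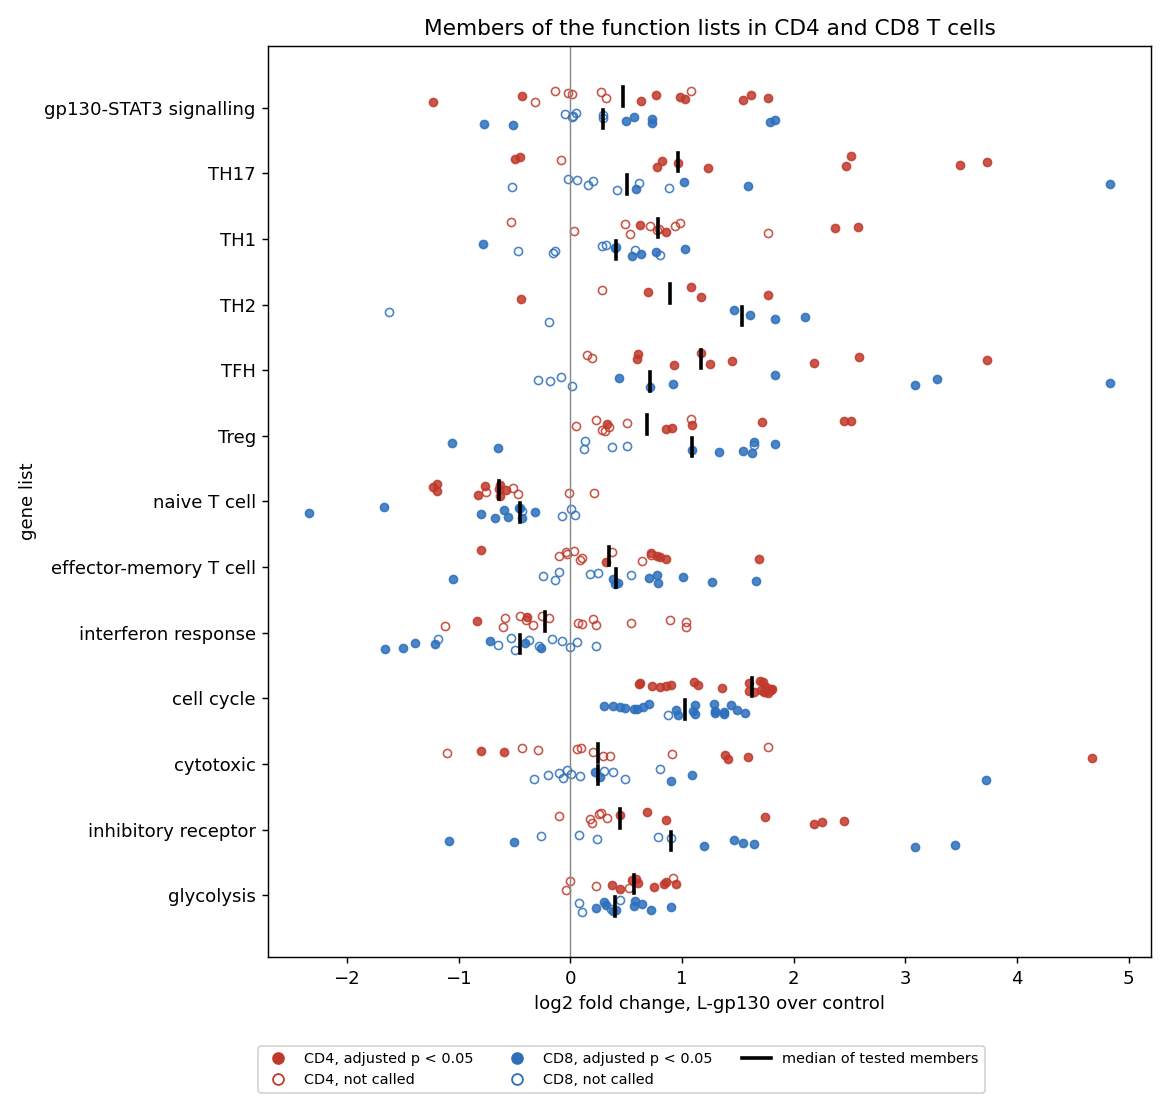
Log2 fold change (horizontal axis) of each tested member of the 13 function lists in CD4 (red) and CD8 (blue) cells, filled where edgeR's adjusted p was under 0.05, with black bars at list medians. All 22 cell cycle genes lie to the right of 0 in both cell types, and naive T cell genes that passed the test lie to the left.

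The CD4 and CD8 responses overlapped. Among 13819 genes tested in both, 675 rose in both cell types, where independent lists would share 164, and 481 fell in both, where independent lists would share 116. Another 25 were called in opposite directions, against 281 for independent lists. Socs3, Bcl3, Stat3, Pdcd1, Lag3, Gzmb and Moxd1 were among the genes up in both. Across genes, which are not independent replicates, log2 fold changes had a Pearson correlation of 0.57 and a Spearman correlation of 0.53. No library entered both comparisons, but whether a mouse gave libraries of both cell types is not known. The number called in the same direction, 1156, was 630 without control CD4 replicate 1, 706 without L-gp130 CD4 replicate 6, 673 without L-gp130 CD8 replicate 1 and 714 without L-gp130 CD8 replicate 3.

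**Figure D3:**
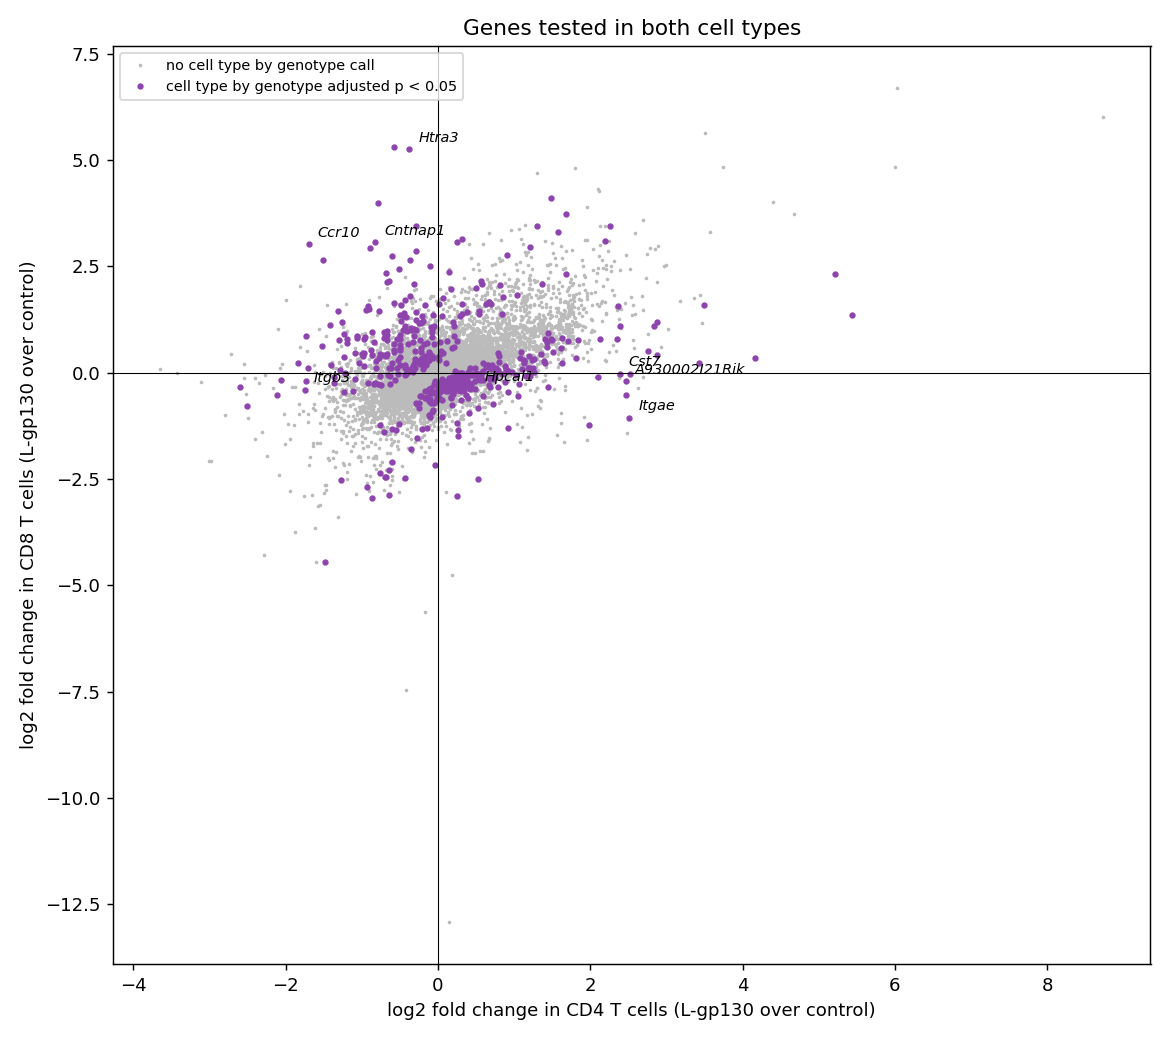
Log2 fold change (L-gp130 over control) in CD4 (horizontal) and CD8 cells (vertical), with 1 point per gene tested in both and purple points for genes with an adjusted p under 0.05 for the cell type by genotype term. Itgae lies at 2.51 in CD4 and -1.06 in CD8 cells.

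Some genes answered differently in CD4 and CD8 libraries, which also differed in how the cells were selected. Depth went with genotype in CD4 libraries alone. Cst7, an inhibitor of lysosomal proteases, rose in CD4 cells (from 16.6 to 83.6 CPM, log2 2.39) and was at 63.3 and 62.4 CPM in control and L-gp130 CD8 cells (log2 -0.021), an interaction of -2.35 ± 0.14 on the log2 scale (edgeR adjusted p = 4.42e-09). Itgae rose in CD4 cells and fell in CD8 cells (interaction -3.57 ± 0.26, adjusted p = 3.51e-07). Htra3 rose in CD8 cells only by the test (interaction 5.51 ± 0.49, adjusted p = 2.25e-06), with a CD4 log2 fold change of -0.38. Itgb3, the integrin beta-3 chain, fell more in CD4 than in CD8 cells (log2 -1.75 and -0.40; interaction 1.38 ± 0.13). Hpcal1, a calcium sensor, rose in CD4 (log2 0.49) and fell in CD8 cells (-0.38; interaction -0.79 ± 0.07). The chemokine receptor gene Ccr10 fell in CD4 (log2 -1.70) and rose in CD8 cells (3.02; interaction 4.63 ± 0.44). Cntnap1 had CD4 and CD8 log2 fold changes of -0.83 and 3.07 (interaction 3.70 ± 0.35). Ccr10 (chromosome 11, 101172997 to 101175443) lies inside the span of Cntnap1 (101170523 to 101190724) on the other strand. Unstranded reads of any exon sequence that they share cannot be told apart, and whether their exons overlap was not checked. A930002I21Rik, a gene without a known product, rose in CD4 cells (log2 2.47) and was at -0.20 in CD8 cells (interaction -3.06 ± 0.30).

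Of 13 tested TH17 genes, 1 had a positive and 4 had a negative interaction by the test (3 and 6 adjusted over the list alone). The 4 were Il23r (-2.97), Il17re (-2.71), Il1r1 (-1.72) and, with few reads, Il22 (-4.82), and the other was Ahr (0.92), all chosen after their values were seen. Camera called the log2 fold changes of the TH17 list lower in CD8 than in CD4 cells (adjusted p = 0.0270, and adjusted p = 0.890 with an estimated correlation). Batf rose in both cell types and less in CD8 cells (interaction -1.02). Hif1a (-0.75), Cxcr5 (-1.02) and Sh2d1a (-0.76) rose in CD4 cells and did not pass the test in CD8 cells. Lag3 (1.202) and Pdcd1 (1.05) rose in both, and by more on the log2 scale in CD8 cells, where control levels were lower. Ahr and Foxp3 (1.14) passed the test in CD8 cells alone. These genes, too, were chosen after their values were seen. Log2 fold changes, not levels, were higher in CD8 cells by this test for the TH2, B cell, dendritic cell and mitochondrial lists (camera adjusted p 0.0270 to 0.0440). So were those of the stroma list (0.000925), and those of the monocyte-macrophage list (0.00188) were lower. By gene, 1 of 8 TH2, 1 of 12 B cell, 2 of 11 dendritic cell and 2 of 7 stroma genes had a positive interaction (3, 1, 3 and 4 adjusted over the list alone), and 0 of 12 mitochondrial and 0 of 14 monocyte-macrophage genes had one of either sign (0, and 5 negative, adjusted over the list alone). All 7 list calls were lost with an estimated correlation, where the smallest adjusted p = 0.302. As genes whose L-gp130 effect differs between CD4 and CD8 T cells, edgeR called 545 of 15758, 256 with a higher log2 fold change in CD8 and 289 in CD4 cells. Of the 506 tested in all fits, 191 had effects of the same sign and 315 of opposite sign, and 22 of the latter were called in both cell types. The count was 984 without L-gp130 CD4 replicate 1, 363 without L-gp130 CD4 replicate 6, 236 and 328 without L-gp130 CD8 replicates 1 and 2, and 353 from the joined gene tables.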

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

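Tests of the other cell types in CD4 libraries, and of sex and depth behind the CD8 control split, were chosen only after the result was seen.

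The rise of TFH, inhibitory receptor and TH17 genes in CD4 cells was weighed against sequencing depth, which went with genotype, sequence bias and the share of T cells. The 22 members called up had a median log2 fold change of 1.25. After thinning each library to the smallest total the median kept 100.4% of its value and all 22 calls. Thinning leaves expected ratios unchanged, so this shows only that the calls did not need the deeper control libraries. It cannot tell genotype from anything else that went with depth. With GC and length offsets the median kept 101.8%, which argues against sequence bias as the whole cause. The median of 15 genes of all T cells was 0.031, or 2.51% of that of the members. The median of all tested genes was -0.0051. In libraries selected for CD4+ cells and normalised to most of their genes, genes of all T cells had little room to rise. This value therefore cannot decide on the share of T cells. Active gp130 in the T cells, or another mix of T cell states in these mice, may lie behind the rise, and the libraries hold no test between the 2.

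Transcripts of other cell types moved apart between the genotypes in CD4 libraries. Among 9 such lists 2 called ones, plasma cell and erythroid, had medians above 0 and 5, those of B cells, monocytes and macrophages, dendritic cells, NK cells and stroma, below 0, and all 7 calls were lost with an estimated correlation (adjusted p 0.125 to 0.580). A lower share of every other cell type in L-gp130 libraries would have moved them alike, and 8 of 11 plasma cell genes called up beside 5 of 12 B cell genes called down argue against it. Another makeup of the spleen in L-gp130 mice cannot be told apart from carry-over that differs by cell type, because genotype and spleen go together. The positive selection on CD4 beads could carry along macrophages and dendritic cells, some of which bear CD4.

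CD8 control replicates 1 to 3 and 4 to 6 lay apart on the second principal component. Carry-over of CD4 T cells into replicates 1 to 3 stays open: 70 genes at least 10 times higher in CD4 libraries had a median ratio of 1.67 (1.04 to 2.70 between the quartiles), and Cd4 itself a ratio of 3.03. Some of these genes belong to other cells of the CD4 preparations, and negative selection should remove CD4 T cells. A sex difference of 0 males (2 in each) argues against sex as the cause, and a depth ratio of 1.01 with overlapping totals against depth. The labels name no batch for these libraries, and no biological explanation other than sex was tested.

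Other splits of the same libraries bear on whether chance can be excluded. For CD4 genes 1 of 100 splits gave as many calls, the real one (2836, highest other 1). For CD8 genes it was 1 of 84, again the real one (2996, highest other 583). Chance division of the libraries is therefore an unlikely source of either count. The splits cannot tell genotype from what went with it, such as depth in CD4 cells. The split with 583 calls set control replicates 4 to 6 against the other 6 libraries and points to a structure of the samples. The genes changed by L-gp130 in CD8 T cells numbered 2539 against control replicates 1 to 3 alone and 3685 against 4 to 6 alone. For the interaction 1 of 100 joint splits gave as many (545, highest other 2). These splits leave the effects in each cell type within the spread, so they do not test whether the effects are equal. For the overlap it was also 1 of 100 (1156, highest other 0), but splits that called at most 1 CD4 gene could give no larger overlap, so they do not test it. For the count of CD4 lists 5 of 100 splits gave as many as the real 19 (highest other 21), so chance cannot be excluded for that count under the preset correlation. Many other CD4 splits with 0 called genes still gave 10 or more called lists, and a split with 21 lists was among them. A CD8 split with 0 called genes gave 19 lists. List calls at the preset correlation, their small adjusted p and their gain or loss between fits are therefore weak evidence by themselves. For the count of CD8 lists 1 of 84 splits, the real one, gave as many (20, highest other 19). Leaving out 1 library gave 18 to 20 lists, so a margin of a single list does not exclude chance.

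Single libraries lay far from the rest of their group, measured as the gap to the nearest library over the group's range, in 17 of 162 groups of values (10.5%), where chance gives about 1 in 20. In L-gp130 CD4, replicate 1 did so for Il6st (0.758, at 132 CPM), Gzmb (0.724), Nkg7 (0.675) and Sostdc1 (0.672), replicate 2 for Il9r (0.804) and replicate 4 for Batf (0.629) and Tigit (0.634). In control CD4, replicate 1 did so for Icos (0.6253), Col14a1 (0.777) and Pdlim4 (0.800), replicate 2 for Pgam1 (0.636) and replicate 3 for Sp6 (0.705). In control CD8, replicate 3 did so for Dapl1 (0.760) and Moxd1 (0.841), replicate 4 for Mcm2 (0.708) and Tpi1 (0.794), and replicate 2 for Cd160 (0.777).

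The effect of L-gp130 differed between CD4 and CD8 libraries, by the interaction test, for 545 genes. Those named are Cst7 (log2 difference -2.35), Itgae (-3.57), Htra3 (5.51), Itgb3 (1.38), Hpcal1 (-0.79), Cntnap1 (3.70), Ccr10 (4.63) and A930002I21Rik (-3.06). Among lists, camera's adjusted p for the difference was 0.0270 for TH17, TH2, dendritic cell and mitochondrial genes, 0.0440 for B cell, 0.00188 for monocyte-macrophage and 0.000925 for stroma genes. All 7 of these list calls were lost with an estimated correlation, where the smallest adjusted p = 0.302. The interaction test cannot tell cell type from the selection method, positive for CD4+ and negative for CD8+ cells. Nor can it tell cell type from depth, which went with genotype in CD4 libraries alone. Whether some of the 545 genes changed in cells other than T cells was not tested.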

How the results depend on the processing

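Alternatives with the sex read from Xist and Ddx3y, thinned libraries, GC and length offsets, doubted libraries left out, part of the CD8 controls and joined gene tables were chosen only after the result was seen. All fits could be run, but some named genes and the CD8 stroma list had no value in some settings. Counts stayed within 1.5 times the reported one in 125 cases and not in 28. Stricter thresholds lowered them by construction: an adjusted p under 0.01 left 1272 genes changed by L-gp130 in CD4 T cells, 1249 genes changed by L-gp130 in CD8 T cells, 195 genes whose L-gp130 effect differs between CD4 and CD8 T cells and 417 overlapping genes, and a 2-fold minimum 942, 836 and 239. Fewer samples left 19 CD4 genes in males alone, 133 CD8 genes in females alone and 1740 in males alone. For the interaction DESeq2 called 955 genes and a fit of the joined gene tables called 353, and the cause was not tested. Without a filter its share of higher log2 fold changes in CD8 was 59.9% in place of 47.0%. An estimated correlation left 6 of 19 CD4 and 1 of 20 CD8 lists.

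Leaving out 1 library at a time gave 1411 to 3642 CD4 genes (lowest without L-gp130 replicate 6, highest without L-gp130 replicate 1), 1374 to 2967 CD8 genes, 236 to 984 interaction genes, 630 to 1405 overlapping genes, 18 to 22 CD4 lists and 18 to 20 CD8 lists. Replicate numbers were not taken to pair the samples. Across genes, deviations of same-numbered libraries correlated at -0.42 to 0.36 in CD4 cells (3 of 6 above 0.1, and 1 of 6 closest to its own number). In CD8 cells they did so at 0.08 to 0.43 (2 of 3, and 1), and between L-gp130 CD4 and CD8 libraries at -0.23 to 0.18 (1 of 3, and 1). Between control CD4 and control CD8 the range was -0.049 to 0.40 (4 of 6, and 3). There replicates 2 and 4, which differ in sex by reads, were at -0.049 and 0.027, and the others at 0.225 to 0.40. Sex was not removed from these deviations, so whether some same-numbered control libraries shared a mouse stays open. A replicate block gave 2274 genes changed by L-gp130 in CD4 T cells, 2406 in CD8 cells and 268 interaction genes, and 21 CD4 and 17 CD8 lists. With it camera also called the CD4 cytotoxic (adjusted p = 0.0138), neutrophil (0.00430) and platelet (0.000784) and the CD8 B cell (0.000255) and neutrophil lists (0.000670), and no longer the CD4 NK cell (0.0946) and the CD8 TH1 (0.0742), TH17 (0.1005), gamma-delta (0.0522), erythroid (0.148) and immediate early lists (0.248). With the block Zbtb46 in CD8 turned from 0.30 to -0.069 and the CD4 interferon list turned up (camera adjusted p = 0.641). Of the genes that the rule takes, 7 lost and 5 gained a call in CD4 cells with the block. In CD8 cells 6 lost and 7 gained one. Those lost in CD8 cells included Moxd1 (edgeR adjusted p = 0.0694), Ccl5 (0.0904), Cxcr6 (0.0647) and Gzma (0.0589).

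Of 230 named genes and lists, 7 reversed in some setting (13 cases), none of them called in the reported fit. Without the sex covariate mt-Nd2, mt-Nd5 and mt-Nd6 in CD4 turned to 0.12, 0.090 and 0.20. Cd4 in CD4 cells turned to 0.036 in females alone and 0.015 without both doubted libraries, and ranged from -0.083 to 0.039 over single libraries left out. In CD8 cells Ppbp turned to 0.34 in females alone, and Zbtb46 to -0.021 against control replicates 1 to 3 alone (-0.017 to 0.55 over single libraries). The interferon list in CD4 turned up without L-gp130 replicate 2 (adjusted p 0.00471 to 0.937 over single libraries). Lists that camera did not call turned too: mitochondrial in CD4 without the sex covariate and with the sex read from Xist and Ddx3y (adjusted p 0.170 and 0.545), and in CD8 B cell and neutrophil against control replicates 4 to 6 alone (0.0926 and 0.755), dendritic cell with the block, against control replicates 1 to 3 alone and without L-gp130 replicate 3 (0.673 to 0.869), and platelet against control replicates 4 to 6 alone and without L-gp130 replicate 1 or control replicates 3 or 5 (0.841 to 0.994). The cause was not tested. Over all settings, 54 of the 230 kept both direction and side throughout, 144 lost a call in at least 1 setting (63 where both sexes were in the fit) and 26 gained one. Fry did not call the CD4 B cell, TH1, NK cell, erythroid and monocyte-macrophage lists (adjusted p 0.0550 to 0.212) or the CD8 erythroid and immediate early lists (0.174 to 0.186). It did call the CD8 other T lineage list lower (adjusted p = 0.0213) and the CD8 stroma list higher (0.0375). At this depth most 1.5-fold changes go uncalled in simulated data.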

Other observations

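Counts of the low cytokines and of genes called in opposite directions were chosen for description only after the result was seen.

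The signature cytokines of TH17 cells were rare in both genotypes, and most were left out of the gene test by its filter. In CD4 cells Il17a had 26 counts over all 6 L-gp130 libraries, with reads in each, and 0 in the controls, at least 11.02-fold higher by the exact 95% lower limit (14.55-fold against the floor of 3 counts over the group). Il22 had 96 counts against 1 (ratio 161, counting interval 28.3 to 6433), Il17f 24 against 21 (1.92, 1.02 to 3.62) and Csf2 16 against 35 (0.77, 0.40 to 1.42). In CD8 cells Il17a had 58 counts in 3 L-gp130 libraries and 60 in 6 controls (1.92, 1.32 to 2.80), but did not pass edgeR's test between mice (log2 0.89 ± 0.62, adjusted p = 0.334). There Il22 had 34 and 23 counts (2.94, 1.68 to 5.22) and Il10, an anti-inflammatory cytokine, 35 and 4 (17.4, 6.22 to 67.4), while Il17f had 5 and 22 (0.45, 0.13 to 1.22) and Csf2 22 and 36 (1.21, 0.68 to 2.12). In CD4 cells Il10 had 166 and 126 counts (2.21, 1.74 to 2.81) and did not pass edgeR's test (log2 1.08 ± 0.43, adjusted p = 0.101). The chemokine Ccl20 had 0 counts in L-gp130 and 8 in control CD4 libraries (counting interval of the ratio 0 to 0.98) and 0 in all CD8 libraries. These intervals leave out the spread between mice.

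Of 22 genes called in opposite directions in the cell types with an interaction call, 5 are given here. Cd82, a tetraspanin, rose in CD4 (log2 0.38) and fell in CD8 cells (-0.29). Pou6f1, a transcription factor (-0.50 and 0.38), Padi3, a peptidylarginine deiminase (-0.90 and 2.94), Ppm1j, a phosphatase (-0.97 and 0.46), and Bcl11a, a zinc finger factor abundant in B cells and plasmacytoid dendritic cells (-0.66 and 0.89), fell in CD4 and rose in CD8 cells.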
